A study of Oxytricha trifallax with 14 samples.

How the data were processed

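Vegetative cells of the ciliate Oxytricha trifallax were profiled by sequencing of small RNA, whole-cell DNA and poly(A) RNA. The somatic nucleus of this organism holds its genes on very small chromosomes, each assembled as a contig, and the tables list 15799 contigs with telomeres at both ends. The 14 samples comprise 4 small RNA libraries (WT, dcl-123, dcl-141 and rdrp13), 4 DNA libraries (strain JRB310, an F1 of JRB310 and JRB510 named the WT exconjugant, dcl-141 and rdrp13) and 6 poly(A) libraries (replicates A and B of WT, dcl-141 and rdrp13). Each small RNA and DNA group has 1 library. The WT small RNA sample was a mix of strains JRB310 and JRB510, per the labels. The labels do not say how the mutant lines were made.

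The authors used cutadapt, Bowtie2 and SAMtools, per the submitters' processing notes, which give no versions. The small RNA values are RPKM, per the labels, which point to a table whose name carries the range 17 to 25, read here as lengths in nucleotides. Which reads RPKM was scaled to, and how reads that map to several contigs were placed, is not given in the sources used here. The deposited DNA values are a ratio to mitochondrial DNA, per the labels' name for the table. The formula behind that ratio and any correction for contig length are not given in the sources used here, so its depth is unknown and no counting interval was computed for DNA.

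The poly(A) table has no header line, and its 3 columns of values could not be matched by name to any of the 6 poly(A) samples. These 3 columns were not used, and every comparison of poly(A) RNA planned before the data were examined was left out. The DNA table names 3 libraries, F1, dcl-141 and rdrp13, so the JRB310 DNA library is not analysed here and F1 served as the only DNA control. DNA values are filled for 12203 rows and blank for the last 3596.

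A further limit concerns the contig names in the DNA table. The small RNA and DNA tables list the same 15799 names in the same order. Binned along that order, the F1 DNA level carried 4.83% of its log2 variance between 50 equal bins, above the highest value of 1000 random orders, 0.721%. The WT small RNA level carried 0.833% over the whole table, also above the highest of its random orders, 0.504%, and 0.553% over the rows with DNA values, where the highest was 0.776%. Sorting the DNA rows alphabetically by their printed names lowered the DNA value to 0.547%, while the same sorting raised the small RNA value over the whole table to 2.79%. The names beside the DNA values are doubted because the DNA level varied along the rows, this was lost on sorting by name, and no relation to small RNA was found. A row order that follows some property of the DNA would also give the first of these, so right names are not excluded. DNA results compare libraries within a row, which needs no name, no contig is named for DNA, and relations between small RNA and DNA are given as the deposited rows pair them, with nothing read from them. Contig lists that cross the assays were not run for the same reason.

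Small RNA values were compared as log2(RPKM + 1) over contigs with a mean of at least 1 RPKM over the 4 libraries. A fold change on this scale understates the change of low contigs. DNA values were compared as log2 ratios without a pseudocount over rows above 0 in all 3 libraries with a mean at or above the 10th percentile. With 1 library per group there is no replicate check, so no difference between groups was tested and no p-value is given. Shares of contigs at least 2-fold lower or higher carry Wilson 95% intervals, and medians carry 95% bootstrap intervals from 1000 draws. Both cover the sampling of contigs only, and contigs are not independent replicates. Correlations across contigs are Spearman's rho with 1000 bootstrap draws. A list's median was set against 10000 random lists of the same size matched on mean level. The DNA lists are defined by level, so their random lists were drawn from all rows kept. The 2 small RNA lists defined by level were given no level-matched percentile and are set beside the medians of all contigs.

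Small RNA values proved to be whole multiples of a contig-specific step, within a relative tolerance of 1.2e-05, in 15796 contigs. This gave read numbers per contig and library, up to a factor that the 4 libraries of a contig may share, which makes them lower limits. The inverse of the step served as relative contig length. On simulated reads the step recovered all 4 numbers in 91.3% of contigs, and the WT total came to 95.5% of the true one. The recovered totals were 3458044 reads for WT, 2809047 for dcl-123, 3118103 for dcl-141 and 345428 for rdrp13, with medians of 142, 92, 117 and 5 reads per contig. One rdrp13 read was worth 2.59 WT reads in RPKM, so the rdrp13 library was the shallow one. In simulated data with counting error only, a 4-fold fall passed the 2-fold limit in 95.5% of changed contigs for dcl-141, 95.7% for dcl-123 and 84.2% for rdrp13. Unchanged contigs passed it in 0.00682%, 0.0273% and 2.49%. A 2-fold fall passed the limit in only 19.8%, 22.3% and 41.8% of changed contigs, in the same order, so counts of 2-fold falls miss many falls of that size. The simulated depths were set by the recovered totals, which include any general fall. For rdrp13 this gives fewer reads than its normalizing total, 0.386 of that of WT, would give. In simulated DNA values with a noise SD of 0.2, all rows given a 4-fold fall passed the limit. That noise was assumed, since the DNA depth is unknown, so this does not measure how many such falls the DNA libraries would show. Ratios of single contigs carry exact binomial 95% intervals from the read numbers, which cover counting error only, since reads without molecular identifiers are not independent molecules. A library at 0 reads was set to a floor of 3 reads.

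No table used here pairs the contigs with gene names. The reference table of 810 genes, from the MIC v2.0 assembly of the germline genome, matched 0 of the contig names. Contigs are therefore given by their names in the small RNA table, at most 2 that rose and 2 that fell per comparison. By the rule set before the data were examined, these were the contigs with the largest changes among the upper 50% by mean level, for the dcl lines ranked by the smaller of the 2 changes. Alternatives covered the pseudocount, the filters, the scaling of libraries, the fold limit and the correlation measure. For small RNA changes, equal medians were set by shifting log2(RPKM + 1), so the added 1 RPKM was scaled too. Equal summed RPKM scaled the RPKM before 1 was added. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.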

Results

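The study asked what part small RNAs play in gene dosage in Oxytricha trifallax, per its title. Small RNA was measured in WT cells and in the mutant lines dcl-123, dcl-141 and rdrp13, and DNA copy level in an F1 wild type and in dcl-141 and rdrp13, with 1 library per group. By convention dcl names genes for Dicer-like enzymes, which cut double-stranded RNA into small RNAs, and rdrp names genes for RNA-dependent RNA polymerases, which make double-stranded RNA. No difference below has a replicate check.

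In WT, nearly every chromosome carried small RNAs. Of 15799 contigs, 12 were at 0 RPKM in WT, 39 in dcl-123, 19 in dcl-141 and 922 in rdrp13, and 0 contigs were at 0 in all 4 libraries. The median contig stood at 8.29 RPKM in WT, 3.999 in dcl-123, 4.99 in dcl-141 and 0.725 in rdrp13. Summed over contigs, the mutants held 0.635, 0.690 and 0.340 of the WT RPKM, in the same order. Small RNAs were spread more evenly in WT, where the top 1% of contigs held 12.7% of the RPKM, and were concentrated in rdrp13, where the top 1% held 58.0%. The dcl lines lay between, at 18.0% in dcl-123 and 15.8% in dcl-141. Shorter contigs carried somewhat more small RNA per kilobase in WT, with a rho of -0.18 between relative length and RPKM across 14357 contigs.

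Small RNAs were lower across most contigs in both dcl lines, and more so in dcl-123. Among 14358 contigs, 84.96% were lower by any amount in dcl-141 than in WT and 87.1% were lower in dcl-123. The median log2 change was -0.58 in dcl-141 (95% interval -0.59 to -0.57) and -0.84 in dcl-123 (-0.85 to -0.83). The median RPKM ratios to WT were 0.625 and 0.496. A fall of at least 2-fold was seen in 2879 contigs in dcl-141 (20.1%, Wilson 95% interval 19.4 to 20.7%) and in 5629 in dcl-123 (39.2%, 38.4 to 40.0%). A rise of at least 2-fold was seen in 214 contigs in dcl-141 (1.49%, 1.30 to 1.70%) and 301 in dcl-123 (2.10%, 1.87 to 2.34%). The general fall rests on the deposited scaling of the libraries. With all libraries brought to the same median, 3.29% of contigs were lower and 6.23% higher in dcl-141, and 4.15% were lower and 10.3% higher in dcl-123. At equal summed RPKM, 6.01% were lower in dcl-141 and 12.2% in dcl-123.

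Single chromosomes with small RNA in WT had nearly none in the dcl lines. The WT sample mixed strains JRB310 and JRB510, so a difference in strain was not told apart from a loss. The intervals of single contigs are not adjusted for picking the largest changes. Both limits hold for rdrp13 as well. Contig11699.0 stood at 248 RPKM in WT (2885 reads), 0.262 in dcl-123 (4 reads) and 0.127 in dcl-141 (2 reads). This is a 947-fold difference for dcl-123 (exact 95% interval 370 to 3479) and a 1945-fold difference for dcl-141 (538 to 16067). Contig9834.0 fell from 25.4 RPKM to 0.164 in dcl-123 and 0.133 in dcl-141, which is 155-fold (71.0 to 424) and 191-fold (81.5 to 591) lower. The largest rises shared by both lines were in Contig22209.0 and Contig17607.0. Contig22209.0 went from 2.05 RPKM in WT (31 reads) to 19.4 in dcl-123 and 22.9 in dcl-141, which is 9.50-fold (6.59 to 14.2) and 11.2-fold (7.76 to 16.6) higher. Contig17607.0 rested on 7 reads in WT and was 15.9-fold (7.51 to 40.2) higher in dcl-123 and 10.9-fold (5.11 to 27.8) higher in dcl-141. Contig22209.0 and Contig17607.0 were also higher in rdrp13, by 2.59-fold (1.52 to 4.41) and 13.7-fold (6.03 to 36.4). They are among the 3 contigs at least 2-fold higher in all 3 mutant lines. A low value in the shared WT library was not told apart from a rise in the mutants.

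**Figure D1:**
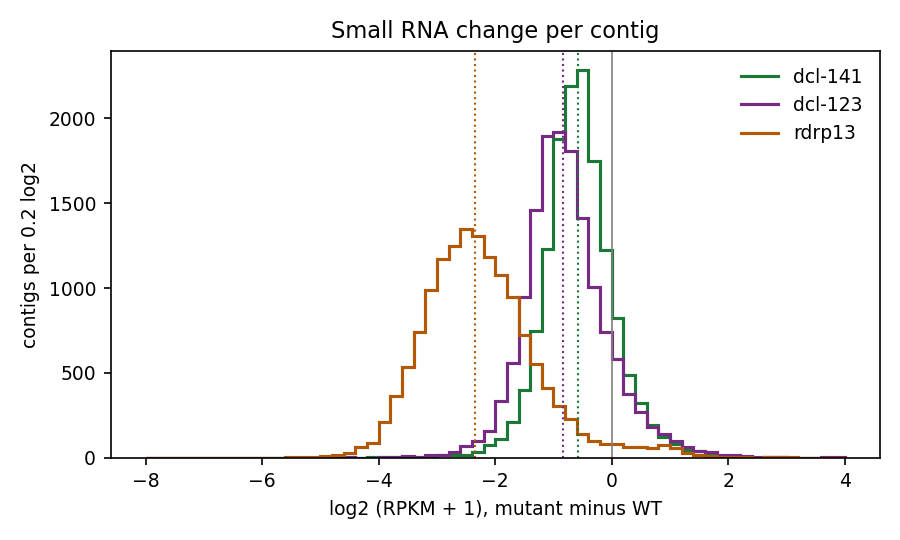
Number of contigs (y axis, per 0.2 log2 unit) by small RNA change against WT (x axis, log2 of RPKM + 1, mutant minus WT) for dcl-141, dcl-123 and rdrp13, 1 library each, with dotted lines at the medians and a grey line at 0; the outermost bins also take changes beyond the axis. The medians lie at -0.58, -0.84 and -2.34, and rdrp13 has a low shoulder of contigs around 0 and above.

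The 2 dcl lines resembled each other more than either resembled WT. Across contigs, the rho between their small RNA levels was 0.90, against 0.79 for dcl-123 with WT and 0.83 for dcl-141 with WT. Directly compared, dcl-141 stood above dcl-123 by a median log2 difference of 0.22 (0.22 to 0.23), with 571 contigs (3.98%, 3.67 to 4.31%) at least 2-fold higher and 165 (1.15%, 0.987 to 1.34%) at least 2-fold lower in dcl-141. That balance rests on the scaling, since with libraries brought to the same median it turned, to 1.69% higher and 2.60% lower, while at equal summed RPKM it stayed, at 3.80% higher and 1.86% lower. A pseudocount of 0.1 RPKM gave 8.77% higher and 2.05% lower. A few chromosomes set the lines apart by far more. The widest gaps in the upper 50% by level, singled out after their values were seen, were in Contig20269.0 and Contig19436.0. Contig20269.0 stood at 281 RPKM in WT, 51.6 in dcl-123 (148 reads) and 1.70 in dcl-141 (5 reads). Contig19436.0 stood at 91.8 RPKM in WT, 0.130 in dcl-123 (2 reads) and 30.998 in dcl-141 (488 reads).

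In rdrp13, small RNAs were lower on nearly all chromosomes and by far more than in the dcl lines. Of the 14358 contigs, 13038 were at least 2-fold lower than in WT (90.8%, 90.3 to 91.3%) and 132 at least 2-fold higher (0.919%, 0.776 to 1.09%). The median log2 change was -2.34 (-2.36 to -2.33), and the median RPKM ratio to WT was 0.0893, an 11.2-fold difference. Small RNAs of Contig11699.0, the contig that led the falls in the dcl lines, were at 0 reads in rdrp13. Set to the floor of 3 reads, this is 371-fold lower, while the exact 95% interval of the fall starts at 302-fold. Contig20269.0 fell from 281 RPKM to 1.19 on 1 read, a 237-fold difference with an exact interval of 42.3 to 9363. Contig20057.0 rose from 3.29 to 61.6 RPKM, 18.7-fold (12.8 to 28.4), and Contig4608.0 from 5.03 to 62.2 RPKM, 12.4-fold (10.03 to 15.3). With libraries brought to the same median, 7.45% of contigs were lower and 18.2% higher, and at equal summed RPKM 69.8% were lower. The shift to equal medians also moves the floor of low contigs. The log2 change of Contig11699.0 went from -7.96 to -5.46 under it, but stayed at -7.96 at equal summed RPKM. The shares at equal medians thus come partly from a moved floor. Low read numbers in rdrp13, at a median of 5 per contig, limit statements on single contigs far more than on the whole. They hold the fall itself as well as lower depth, since the normalizing total of rdrp13 was 0.386 of that of WT.

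On the deposited scaling, a minority of chromosomes were at or above their WT small RNA level in rdrp13. In 470 contigs (3.27% of those compared) the rdrp13 level was at or above WT, with a median of 29.6 RPKM in rdrp13 and 19.2 in WT, and a median of 173 rdrp13 reads. These contigs held 66.4% of all rdrp13 RPKM and 11.95% of that in WT. In the other 13888 contigs the medians were 0.771 RPKM in rdrp13 and 9.08 in WT. The class rests on the deposited scaling, since 8186 contigs were at or above WT with libraries brought to the same median.

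**Figure D2:**
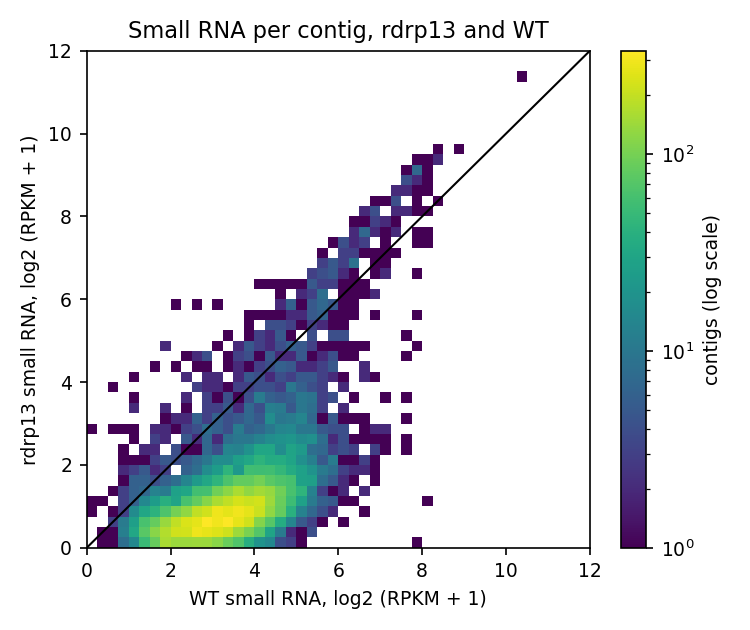
Small RNA level of each contig in rdrp13 (y axis) against WT (x axis), both as log2 of RPKM + 1, with colour for the number of contigs on a log scale and a line where both are equal. The bulk of the 14358 contigs lies far below the line, and the 470 contigs at or above WT lie on or above it.

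Changed chromosomes were partly shared between the mutants, in counts that all rest on the same WT library and on the deposited scaling. Both dcl lines were at least 2-fold lower in 2380 contigs and at least 2-fold higher in 137, where independent lists of the same sizes would share 1129 and 4.49. For dcl-141 and rdrp13 the shared contigs numbered 2794 lower and 16 higher, against 2614 and 1.97 for independent lists. For dcl-123 and rdrp13 they numbered 5499 lower and 7 higher, against 5112 and 2.77. With libraries brought to the same median the shared contigs numbered 209 lower and 683 higher for the dcl lines (19.6 and 92.0 in independent lists), 137 and 623 for dcl-141 with rdrp13 (35.2 and 162), and 191 and 836 for dcl-123 with rdrp13 (44.4 and 269). At equal summed RPKM they numbered 531 and 448, 721 and 135, and 1510 and 160, in the same order. Unchanged libraries simulated against the WT library by read counting shared 0 lower and 1 higher for the dcl lines, 2 and 1 for dcl-141 with rdrp13, and 1.5 and 1 for dcl-123 with rdrp13. The rho between log2 changes was 0.74 for dcl-141 with dcl-123, 0.47 for dcl-141 with rdrp13 and 0.52 for dcl-123 with rdrp13. The simulated libraries gave 0.43, 0.19 and 0.19. For these rho values they were given the recovered read totals, so the general fall counted as lower depth. This adds counting error to them, and the simulated rho values may be too low. The covariances were 0.346, 0.298 and 0.371, against simulated values of 0.0144, 0.0145 and 0.0150. The simulation covers counting error only, so part of the excess in the counts, too, may come from the shared WT library. With no shared library, the change of dcl-141 against WT and the difference between dcl-123 and rdrp13 had a rho of 0.11. A change that dcl-141 shares with dcl-123 raises this rho, while one it shares with rdrp13 lowers it. It therefore cannot tell how much of the sharing comes from the WT library.

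Contigs grouped by their small RNA in the dcl lines differed from other contigs in rdrp13, and the reverse held, but noise in the shared WT library pushes both the same way. The 96 contigs at least 4-fold lower in both dcl lines had a median log2 change of -3.29 in rdrp13, against -2.34 for all contigs and below all 10000 matched random lists. In rdrp13, 91 of them were at least 2-fold lower and 0 higher. The 137 contigs at least 2-fold higher in both dcl lines had a median of -0.66 in rdrp13, above all matched random lists, with 45 at least 2-fold lower, 3 higher and 89 between. This list rests on the scaling, since with libraries brought to the same median it held 683 contigs with a median of 1.41 in rdrp13, against 0.15 for all contigs, and 0 of them were lower. At equal summed RPKM it held 448, with a median of 0.13 against -1.50. The 9324 contigs at least 4-fold lower in rdrp13 had medians of -0.71 in dcl-141 and -1.01 in dcl-123, below all matched random lists. Relative to all contigs these medians differed by -0.95, 1.69, -0.13 and -0.17, in the order given. Lists of the same sizes with the most extreme changes in simulated unchanged libraries, which share the WT library by counting error only, gave -0.34, 0.34, -0.016 and -0.016. With libraries brought to the same median the lists of 96 and 9324 held 19 and 60 contigs, with medians of -0.97 in rdrp13, and of -0.93 in dcl-141 and -0.90 in dcl-123. At equal summed RPKM they held 36 and 4171 contigs. Their medians were -2.65 in rdrp13, and -0.36 in dcl-141 and -0.61 in dcl-123, against -1.50, -0.13 and -0.30 for all contigs. The 1580 contigs richest in small RNA had medians of -0.36 in dcl-141, -0.40 in dcl-123 and -2.26 in rdrp13. The 1435 contigs with the lowest levels had medians of -0.45, -0.66 and -1.37. The medians of all contigs were -0.58, -0.84 and -2.34. The log2(RPKM + 1) scale limits how far low contigs can fall, so these values do not show that the lowest contigs fell less.

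DNA copy level relative to mitochondrial DNA was lower throughout in dcl-141 and slightly lower in rdrp13 than in F1. Over 10972 rows, dcl-141 stood at a median ratio of 0.333 to F1, 3.01-fold lower (median log2 ratio -1.59, -1.60 to -1.58), and 10182 rows (92.8%, 92.3 to 93.3%) were at least 2-fold lower with 8 (0.0729%, 0.0370 to 0.144%) higher. In rdrp13 the median ratio was 0.835 (log2 -0.26, -0.27 to -0.25), with 275 rows (2.51%, 2.23 to 2.82%) at least 2-fold lower and 34 (0.310%, 0.222 to 0.433%) higher. A pseudocount at the 5th percentile of the F1 values, which damps ratios of low values, took the share lower to 55.1% in dcl-141, with a median of -1.04, and to 1.25% in rdrp13. A common factor made up most of the dcl-141 difference. With libraries brought to the same median, 187 rows (1.70%) were lower and 174 (1.59%) higher in dcl-141, and 147 (1.34%) lower and 102 (0.930%) higher in rdrp13. A ratio to mitochondrial DNA cannot tell less chromosomal DNA from more mitochondrial DNA in a library. No second wild type is analysed here as a yardstick.

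Relative to the common factor, most chromosomes lay within 2-fold of their F1 level, and in rdrp13 the rows at both ends of the range by level shifted. The SD of log2 levels was 1.05 in F1, 1.12 in dcl-141 and 0.92 in rdrp13. Rows in the top 5% by mean level, 610 in number, had a median rescaled log2 change of -0.29 in rdrp13, with 565 below 0, and of 0.12 in dcl-141, with 197 below 0. The 1097 rows with the lowest levels had medians of 0.26 in rdrp13 and 0.047 in dcl-141, where the medians of all rows were -0.0028 and 0.048. Both lists were chosen by a mean level that holds both terms of each ratio, so their place among random lists is no separate support. In rdrp13, the list of highest levels lay below and that of lowest levels above all of 10000 random lists. In dcl-141, the list of highest levels lay above all random lists and that of lowest levels above 46.4%. Over all rows, however, the dcl-141 ratio fell slightly with level, with a rho of -0.14 with the F1 level and -0.11 with the rdrp13 level. The matching values for rdrp13 were -0.65 with the F1 level and -0.56 with the dcl-141 level. The widest single falls after rescaling were -8.68 in dcl-141, where a row at 35.3 per 100000 in F1 and 31.2 in rdrp13 stood at 0.0277, and -8.25 in rdrp13, where a row at 24.1 in F1 and 13.2 in dcl-141 stood at 0.0660. The widest rise in dcl-141 took a row from 4.37 in F1 to 124, and 1 row led in rdrp13 and came second in dcl-141, at 1.53 in F1, 7.84 in dcl-141 and 17.1 in rdrp13.

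**Figure D3:**
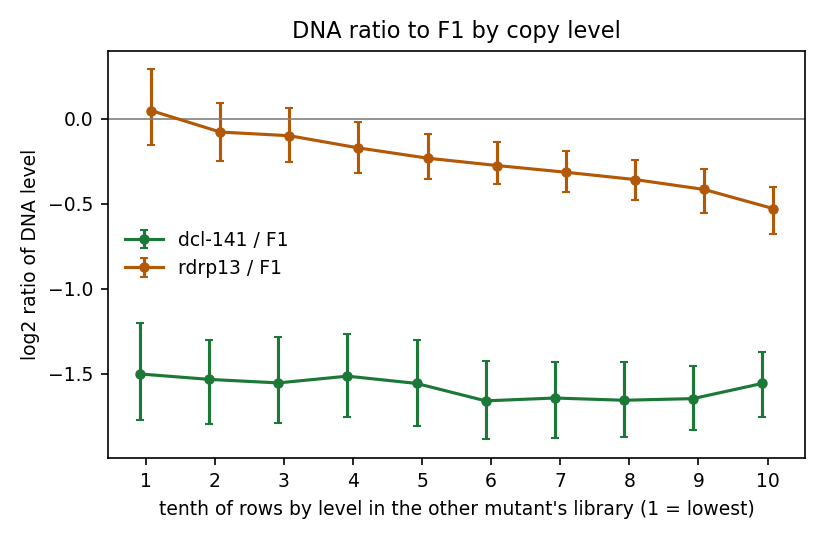
Median log2 ratio of DNA level to F1 (y axis, bars from the 25th to the 75th percentile of rows) for dcl-141 and rdrp13 in 10 equal groups of rows (x axis) sorted by the level in the other mutant's library, which is not part of the ratio. In rdrp13 the median goes from 0.05 in the lowest group to -0.53 in the highest, while in dcl-141 it stays between -1.66 and -1.50.

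The DNA changes of the mutants were weakly correlated over all rows. Rows higher in both mutants and rows moved in opposite directions were each more numerous than in independent lists. The rho between the log2 ratios of dcl-141 and rdrp13 to F1 was 0.13, and both share the F1 library, whose counting error is unknown. After rescaling, 2 rows were at least 2-fold lower in both mutants and 18 higher in both, where independent lists would share 2.51 and 1.62. Rows that moved in opposite directions numbered 6 and 8, against 2.33 and 1.74. Part of the excess in rows higher in both may come from the shared F1 library. The excess in opposite moves would not, since noise in a shared library makes such moves rarer. Independent lists are thus no yardstick for unchanged rows.

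Whether chromosomes that lose small RNA change in copy level could not be settled with the rows as deposited. As they pair the names, the rho between small RNA change and DNA change was 0.011 in dcl-141 (-0.0079 to 0.030) and 0.0034 in rdrp13 (-0.015 to 0.022) across 9917 contigs. The rho between WT small RNA level and F1 DNA level was 0.0068 (-0.014 to 0.026). The names beside the DNA values are doubted, so these values do not show that small RNA and copy level are unrelated. Poly(A) RNA was not analysed here.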

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

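With 1 library per group, none of the differences given here was tested. They count contigs at which 2 lines moved at least 2-fold in opposite directions against the same control. In small RNA, 3 contigs were higher in dcl-123 and lower in dcl-141, and 11 were lower in dcl-123 and higher in dcl-141. Both dcl lines were higher while rdrp13 was lower in 45 contigs, and both dcl lines were lower while rdrp13 was higher in 7. All 4 counts lie below those of independent lists of the same sizes, which would give 60.4, 83.9, 124 and 21.9, in the order given. All these changes share the WT library, whose noise makes opposite moves rarer. Independent lists are thus no yardstick for unchanged contigs, and nothing is read from the shortfall. They rest on the deposited scaling, under which 90.8% of contigs were lower in rdrp13. With libraries brought to the same median the counts were 6, 4, 0 and 9, against 48.7, 37.1, 50.9 and 37.98. A pseudocount of 0.1 RPKM gave 4, 17, 83 and 12, a mean of at least 10 RPKM gave 3, 7, 31 and 0, and equal summed RPKM gave 4, 12, 34 and 10. In DNA, after libraries were brought to the same median, 6 rows were higher in dcl-141 and lower in rdrp13, and 8 were lower in dcl-141 and higher in rdrp13. Independent lists of the same sizes would give 2.33 and 1.74 such rows, but they are no yardstick for unchanged rows here either.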

How the results depend on the processing

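The alternatives were chosen before the data were examined, except the equal summed RPKM, the filter without rdrp13, the DNA pseudocount from F1 the 1.5-fold limit with rescaling and the random lists drawn from all contigs for small RNA lists defined by level, which were added after seeing the data. Values are given in the order dcl-141, dcl-123, rdrp13 against WT, then dcl-141 against dcl-123, unless named otherwise. Bringing the small RNA libraries to the same median, which by construction centres the changes, turned the sign of the median log2 change to 0.041, 0.048, 0.15 and -0.040. The percent lower became 3.29, 4.15, 7.45 and 2.60, and the percent higher 6.23, 10.3, 18.2 and 1.69. Equal summed RPKM gave medians of -0.13, -0.30, -1.50 and 0.14, with 6.01, 12.2, 69.8 and 1.86% lower, and 4.49, 6.14 and 4.11% higher against WT. A pseudocount of 0.1 RPKM gave medians of -0.67, -0.99, -3.30 and 0.27, with 28.3, 49.4, 93.8 and 2.05% lower, and 2.12% higher in dcl-141, 2.56% in dcl-123 and 8.77% between the dcl lines. Without a filter the medians were -0.54, -0.78, -2.24 and 0.21, with 18.4, 36.2 and 84.5% lower against WT and 3.66% higher between the dcl lines. A mean of at least 10 RPKM gave medians of -0.48, -0.62, -2.72 and 0.11, with 17.6, 31.5, 83.05 and 2.27% lower, and 3.67, 5.84 and 3.04% higher against WT. At a 4-fold limit 1.30, 2.99, 64.9 and 0.188% were lower and 0.0836, 0.313, 0.118 and 0.265% higher. The filter without the rdrp13 library moved no dcl value beyond its interval. For DNA, dcl-141 first and rdrp13 second, equal medians gave 1.70 and 1.34% lower and 1.59 and 0.930% higher. No filter beyond values above 0 gave 91.5 and 2.82% lower, 0.156 and 0.599% higher, and a median of -0.25 in rdrp13. The filter at the 50th percentile gave medians of -1.62 and -0.36, 95.1 and 3.08% lower, and 0.0984% higher in rdrp13. A pseudocount at the 5th percentile of F1 gave medians of -1.04 and -0.20, 55.1 and 1.25% lower, and 0.00911 and 0.0729% higher. A 1.5-fold limit gave 98.7 and 11.2% lower and 1.63% higher in rdrp13, and with rescaling 5.64 and 3.91% lower and 8.69 and 5.32% higher. Stricter filters moved the rho of dcl-141 with dcl-123 to 0.80, that of dcl-141 with rdrp13 to 0.60 and that of the DNA ratios to 0.048. The same filters, which left 1133 contigs, gave 0.057 for small RNA change with DNA change in dcl-141 (-0.0023 to 0.11) and 0.056 for WT levels (-0.0031 to 0.12). Pearson's r was 0.75 for the dcl lines and 0.10 for the DNA ratios. In all, with the named contigs, shared and flagged counts and small RNA lists included, 151 values moved beyond the interval of the main value or over 1.5 times for a count, 6 turned and the rest stayed within it. The contigs at least 2-fold higher in both dcl lines had a median log2 change in rdrp13 of 1.41 at equal medians and 0.13 at equal summed RPKM, where the main value was negative. Scalings, pseudocounts, fold limits and filters set the scale or the contigs by construction, and for the correlations the cause was not tested. No named contig changed direction under any small RNA alternative run for it, in the 2 contigs that set the dcl lines apart as in the others.

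No paired analysis was possible because the replicate letters belong to the poly(A) libraries, whose columns carry no names. The poly(A) comparisons with all their alternatives, the poly(A) correlations, the list by poly(A) level and its set tests, F1 against JRB310 with its alternatives, the pseudocount from JRB310 and the DNA correlation with disjoint libraries were not run. Low read numbers limit rdrp13 most, at a median of 5 reads per contig.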

Other observations

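All tests weighed in this part were chosen only after the results were seen. On the log2(RPKM + 1) scale, the fall of small RNA varied little with chromosome length. From the shortest to the longest of 10 equal groups, the median log2 change stayed between -2.45 and -2.07 in rdrp13, between -0.91 and -0.73 in dcl-123 and between -0.62 and -0.56 in dcl-141. The median WT level went from 12.2 RPKM in the shortest group to 6.43 in the longest, and this scale limits how far lower levels can fall. The -2.07 of the longest group in rdrp13 thus does not show a smaller fall there.

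The first pattern weighed is the set of 470 contigs whose small RNA level in rdrp13 was at or above WT. Counting error in the shallow rdrp13 library about the median ratio of all contigs, 0.0893, is argued against. Of these contigs, 95.5% (449) had a ratio above that median beyond an exact interval whose error level was divided by 14358. The test does not cover contigs with a true ratio between that median and WT that counting error lifted to WT. For the biological hypothesis that small RNAs on these contigs depend on neither gene, the same number of contigs chosen by rdrp13 level alone had median log2 changes of -0.17 in dcl-141 (95% bootstrap interval -0.23 to -0.10) and -0.25 in dcl-123 (-0.30 to -0.18). These lie between 0 and the medians of all contigs, -0.58 and -0.84, and where no change would lie depends on the scaling, so the hypothesis stays open. RNA fragments of other kinds that map to these contigs, and how reads of several origins were placed, were not tested.

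The second pattern is the fall of the rdrp13 DNA ratio with copy level. Noise in the F1 library enters both the ratio and the F1 level, where the rho was -0.65, but the rho with the level in the dcl-141 library, which is in neither, was still -0.56 (-0.57 to -0.54). A wider range of levels in F1 than in both mutants is argued against by the ratio of dcl-141 to F1, whose rho with the rdrp13 level was -0.11 (-0.13 to -0.09). What remains lies mostly on the side of the rdrp13 library. A narrower range from library preparation and a real levelling of copy number in this line were not tested and stay open with 1 library.

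The third pattern is the lack of any relation between small RNA and DNA by contig name, where the largest absolute rho of 25 pairs of measures was 0.016. Right names beside levels that are unrelated stay possible, since the 4.83% of the DNA variance between 50 bins of rows, against at most 0.721% in random orders, could come from a row order that follows a property of the DNA. Another candidate is that the values stand in alphabetical order of contigs beside names in another order. Over the 50 bins, the DNA level by row and the small RNA level by alphabetical order had a rho of 0.33, but 4 of 49 circular shifts gave as much and the highest gave 0.42, so this order was not established.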
